A study of Mus musculus with 24 samples.

How the data were processed

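RNA was measured in adipose stromal cells that had been sorted by flow cytometry from the gonadal fat of male C57Bl/6 mice. Per the labels, the tissue was minced and digested with collagenase, live cells were sorted into media, and RNA was purified after centrifugation. The gating markers other than CD11c are not given in the sources used here. Per the labels' protocols, RNA was amplified as whole-transcript cDNA with a NuGEN kit, and the cDNA was labelled with biotin and hybridised to single-colour arrays, 1 array per sample. Per the series design, a sample was a pool: ND macrophages and dendritic cells came as 2 pools of cells from 4 mice, and the HFD samples and all preadipocytes as 3 pools of 3 to 4 mice each. Whether the WL samples were pools is not given in the sources used here. The p-values therefore measure the spread between these samples, not between single mice.

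The values used were those of the deposited series table, which holds normalized log2 expression values for 41345 probe rows and 24 arrays. Per the submitters' processing notes, the authors used RMA, oligo and limma, with no versions or settings given; whether limma changed the deposited log2 values or was used only for their tests is not stated. RMA corrects background and quantile-normalizes arrays against each other, so that a shift shared by all genes of a sample is removed. The deposited values ranged from -0.02 to 13.1 log2 units, and the median of an array lay between 2.96 and 3.15. Scanner files and probe-level intensities were not used here, so background could not be judged probe by probe. The array median served instead as a floor, a choice made after seeing the data: where a group lay below it, the least difference was the brighter group's mean minus the mean, over the dimmer group's arrays, of the higher of the median and the gene's own value. The number of arrays limits the precision.

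Each array was placed in 1 of 9 groups by the group and replicate number in its title. Probe rows were named from the platform annotation supplied with the table. A single gene symbol was given for 23521 probe rows, several symbols for 1814, and 16010 were not named here. Of the single symbols, 23328 were matched by gene identifier to a current gene table and 0 changed. Rows with several symbols named no gene. Of the 22180 genes with 1 symbol, 1082 had more than 1 probe row and were represented by the row with the highest mean over all 24 arrays. A gene was tested if at least 2 arrays lay above that array's own median, which left 15496 genes. Probe sequences were not used here, so signal shared between near-identical genes, such as the tryptases Tpsb2 and Tpsab1 or members of the Oas, Klr and Trim30 families, could not be separated.

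Differences between groups were tested on the log2 scale with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. A single fit held all 24 arrays with 1 mean per group, which left 15 residual degrees of freedom and a spread shared by all groups. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes within each of 9 comparisons and 2 interactions, with a threshold of 0.05. Log2 differences are given with the standard error (SE) of the fit. The same code was first tested on data simulated on the design. It called 93.9% of genes changed by 3 log2 units in WL against HFD CD11c+ ATM, the lowest of the 9 comparisons. Of genes changed by 1 unit it called from 10.4% (WL against HFD CD11c- ATM) to 35.8% (HFD ATDC against CD11c+ ATM), and 3% and 0% in the HFD and WL interactions, so most changes of that size would be missed. The planted changes loosen the adjusted threshold, so fewer may be called in a comparison with few changed genes. A shifted gene list was called in each simulated comparison, and 1 list that was not shifted was called as well, in ATDC. The simulated genes varied independently, so false list calls that arise from correlated genes were not tested. Fixed gene lists were tested with limma's camera, with an inter-gene correlation preset at 0.01 and p-values adjusted over the lists within a comparison. Of 35 lists, 34 had the minimum of 3 tested members. For each list, members past the threshold were also counted after adjustment over the list alone. Lists share some genes, and a list's name does not say what each member did in these cells.

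Groups, comparisons, tests, gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The rule named, per comparison, the 10 genes with the largest rises and the 10 with the largest falls among those past the threshold whose groups did not overlap on any array (5 and 5 in the 2 comparisons WL CD11c+ against WL CD11c- ATM and HFD ATDC against HFD CD11c+ ATM). It passed over unnamed gene models, olfactory and vomeronasal receptors and antigen receptor segments, and the text may leave members out. It added, for each gene list described, up to 4 members with the largest changes past the threshold, or the largest values where fewer passed, and a fixed set of 24 anchor genes. For interactions it named the 5 largest terms of each sign past the threshold.

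Alternatives were no filter on low values, a fit of only the arrays compared, cyclic loess normalization, an intensity-dependent robust prior, array weights, the mean of a gene's probe rows, the replicate number as a block, an estimated inter-gene correlation, the fry test, and leaving out each array in turn. Where such a leave-out left 1 array in a group, that lone array was assumed to vary like the other groups. Leaving out together 3 arrays that stood apart from their groups (HFD CD11c- ATM replicate 3, HFD ATDC replicate 1 and WL CD11c+ ATM replicate 1) was added after seeing the data. No processing dates or batches are given in the sources used here, so in comparisons of WL with HFD or ND arrays a batch cannot in general be told apart from weight loss. Weeks on diet were recorded here for the WL mice only, so age and time on diet cannot be told apart from it either. Body weights were not used here, and obese and lean stand for HFD and ND.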

Results

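Stromal cells of gonadal fat from male C57Bl/6 mice were sorted into adipose tissue macrophages (ATM) with or without CD11c (an integrin encoded by Itgax), adipose tissue dendritic cells (ATDC) and preadipocytes (PA), the precursors of fat cells. The mice had eaten a normal diet (ND) or a high-fat diet (HFD, 60% fat), or had eaten the HFD for 12 weeks and then gone without it for 8 weeks (weight loss, WL). The 24 arrays fell into 9 groups. There were CD11c- ATM of ND (2 arrays), HFD (3) and WL mice (2) and CD11c+ ATM of HFD (3) and WL mice (3). The others were ATDC of ND (2) and HFD mice (3), and PA of ND (3) and HFD mice (3). CD11c+ ATM of ND mice were not purified, per the series design, because cells were scarce. All differences below are on the log2 scale, given as the estimate ± SE of the limma fit with its Benjamini-Hochberg adjusted p over 15496 genes. Background calls were not used here. Where no array of a group lay above its own median, the mark a gene had to pass to be tested, the size of a difference is not exact, and for the genes named it is also given as at least the distance to that median.

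Marker lists differed between the sorted populations, with overlap. The macrophage identity list had a mean level (mean over arrays of the list's median log2 value) of 10.01 in ND, 9.65 in HFD and 9.25 in WL CD11c- ATM. It was 9.47 in HFD and 9.15 in WL CD11c+ ATM. This list also stood at 8.71 in ND and 8.49 in HFD ATDC, with 9.30 on HFD ATDC replicate 2, and at 4.92 in ND and 7.12 in HFD PA. The dendritic cell identity list stood at 7.97 in ND and 8.28 in HFD ATDC, against 4.80 to 5.73 in the macrophage groups. The preadipocyte and fibroblast identity list stood at 9.77 in ND and 10.09 in HFD PA, and at 6.04 in ND, 7.80 in HFD and 8.73 in WL CD11c- ATM. Arrays of one group correlated across genes with r from 0.878 to 0.982 (median 0.955, 21 pairs), and arrays of different groups from 0.71 to 0.968 (median 0.875, 255 pairs); genes are not independent replicates. The lowest mean correlations with the own group were 0.881, 0.913 and 0.917, on the 3 WL CD11c+ ATM arrays.

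**Figure D1:**
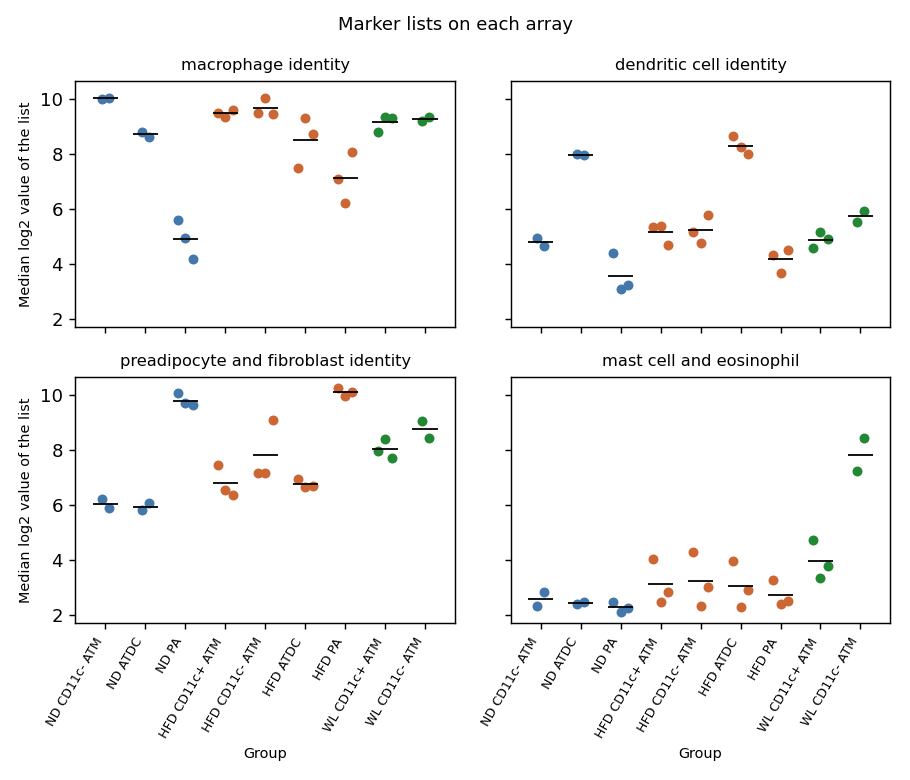
Median log2 value (vertical axis) of 4 marker gene lists on each array (points) in each of the 9 groups (horizontal axis), with the group mean as a black line; blue is ND, orange HFD and green WL. The mast cell and eosinophil list lies at 7.22 and 8.43 on the WL CD11c- ATM arrays and at or below 4.73 on all others.

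The comparison of HFD with ND CD11c- ATM asked what obesity changed in these macrophages (3 against 2 arrays). Genes of matrix proteins and of matrix-degrading proteases rose. Postn (periostin, a matrix protein) was higher by 4.75 ± 0.54 (adjusted p = 0.00019), and by 4.04 without HFD replicate 3, the array with its highest value. Ctsk (cathepsin K, a collagen-degrading lysosomal protease) was higher by 4.53 ± 0.58 (adjusted p = 0.00054). Mmp12, the macrophage elastase, rose by 3.84 ± 0.50, and the proteoglycan gene Lum by 3.77 ± 0.48. The collagen genes Col6a1, Col3a1 and Col1a2 rose by 3.90 ± 0.54, 3.53 ± 0.54 and 3.14 ± 0.42. Mmp9, which encodes gelatinase B, fell by 4.80 ± 0.35 (adjusted p = 2e-07). The secreted phospholipase gene Pla2g2d fell by 4.06 ± 0.53 and the amino acid transporter gene Slc7a13 by 2.86 ± 0.20. Pparg, the nuclear receptor that drives adipogenesis and also acts in macrophages, rose by 2.09 ± 0.29 (adjusted p = 0.0011). All of these stayed past the threshold with each of the 5 arrays left out in turn, and each of the largest rises and falls separated the 3 HFD from the 2 ND arrays without overlap. Itgax (3.25 ± 0.67, adjusted p = 0.028), Cd9 (2.89 ± 0.48, adjusted p = 0.006), Gpnmb (3.65 ± 0.70, adjusted p = 0.018) and Il1b (1.98 ± 0.42, adjusted p = 0.033) also rose, but missed the threshold in leave-outs, with adjusted p up to 0.22, 0.088, 0.17 and 0.44. The arrays whose removal ended these calls were both ND arrays for Cd9, both ND arrays and HFD replicates 1 and 3 for Itgax and Gpnmb, and ND replicate 2 and each HFD array for Il1b. No ND array was above its median for Itgax (a rise of at least 3.02), and 1 of 2 was for Il1b. Adgre1, which encodes the macrophage marker F4/80 (0.32 ± 0.61), and the mannose receptor gene Mrc1 (-0.30 ± 0.61) did not pass (adjusted p = 0.97 for both).

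By list, 9 of 36 genes for fibrillar collagen and extracellular matrix rose and none fell (29 rose adjusted over the list alone). The collagen list had a median of 1.84 and a camera adjusted p = 1.67e-34, or adjusted p = 0.062 with an estimated correlation. In this list 5 genes passed without ND replicate 2. Of 21 matrix remodelling genes 5 rose and 1, Mmp9, fell (12 and 1 adjusted over the list alone). The list had a camera adjusted p = 2.05e-09, or adjusted p = 0.0855 with an estimated correlation. The rises in this list were 2 without ND replicate 1, 3 without HFD replicate 3 and 9 without HFD replicate 2. Of 21 genes of the lipid-associated macrophage list 7 rose (10 adjusted over the list alone), led by Ctsk, Mmp12, Gpnmb and Itgax. This list had a camera adjusted p = 4.26e-15, or adjusted p = 0.0657 with an estimated correlation. Without ND replicate 1 this count was 2, and it was 3 without ND replicate 2, HFD replicate 1 or HFD replicate 3. Of 20 tissue-resident macrophage genes 1 fell (1 adjusted over the list alone). The list had a camera adjusted p = 0.000198, or adjusted p = 0.561 with an estimated correlation. The gene that fell was Timd4, a receptor for dying cells (-2.67 ± 0.55, adjusted p = 0.028), which missed the threshold without either ND array, HFD replicate 1 or HFD replicate 3 (adjusted p up to 0.24). No gene of the 39 of the cell cycle list passed (9 adjusted over the list alone), and 1 passed without ND replicate 2 and 3 without HFD replicate 2. This list had a median of 0.917 and a camera adjusted p = 5.68e-15, or adjusted p = 0.137 with an estimated correlation.

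Markers of other cell types differed. Of 18 genes of the preadipocyte and fibroblast identity list 4 rose (13 adjusted over the list alone, 7 without HFD replicate 2). Of the 18, 6 are also in the collagen list, so these rises may repeat those above. The preadipocyte list had a camera adjusted p = 4.19e-16, or adjusted p = 0.062 with an estimated correlation. Its level was 9.08 on HFD replicate 3, 7.16 and 7.15 on the other HFD arrays, and 6.20 and 5.89 on the ND arrays. The fibrillar collagen and extracellular matrix list stood at 7.70 on HFD replicate 3 against 5.17 and 4.73 on the other HFD arrays, and without that array 6 of its 36 genes passed and its median was 1.12. None of 12 monocyte genes passed (4 higher adjusted over the list alone, 1 without HFD replicate 1), and the list stood at 6.74, 6.89 and 7.17 on the HFD arrays against 5.34 and 6.06 on the ND arrays. The list had a median of 0.928 and a camera adjusted p = 5.72e-05, or adjusted p = 0.062 with an estimated correlation. None of 28 dissociation stress and immediate early genes passed (0 adjusted over the list alone), and the list stood at 7.92, 7.91 and 7.97 on the HFD arrays against 8.48 and 8.39 on the ND arrays. This list had a median of -0.217 and a camera adjusted p = 0.0285, or adjusted p = 0.704 with an estimated correlation. In all, 95 genes passed in limma (68 higher, 27 lower), of which 13 (10 higher, 3 lower) passed in every leave-out. The count was 30 without ND replicate 1, 37 without ND replicate 2, 58 without HFD replicate 1, 176 without HFD replicate 2 and 32 without HFD replicate 3. It was 3 in a fit of these 5 arrays alone, 206 with array weights and 46 without the 3 arrays that stood apart, of which HFD replicate 3 is in this comparison.

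**Figure D2:**
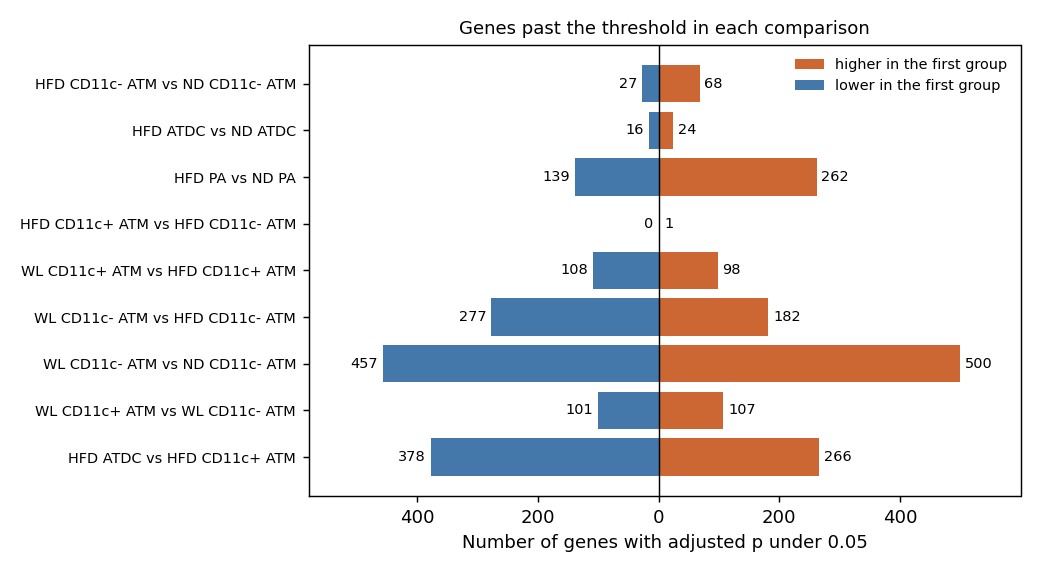
Number of genes with an adjusted p under 0.05 in limma (horizontal axis) in each of the 9 comparisons (vertical axis), with genes higher in the first group to the right in orange and lower ones to the left in blue. The counts run from 1 higher and 0 lower gene between the 2 macrophage subsets of HFD mice to 500 higher and 457 lower genes in WL against ND CD11c- ATM.

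The same diet comparison in ATDC (3 HFD against 2 ND arrays) had 40 genes past the threshold in limma (24 higher, 16 lower). Ctsk was higher by 4.75 ± 0.58 (adjusted p = 0.00077), and Akr1c18, an aldo-keto reductase that inactivates progesterone, was lower by -3.84 ± 0.46 (adjusted p = 0.00077). Both separated the diets on every array and passed in every leave-out, as did 5 of the 40 genes. Gpnmb (3.41 ± 0.70), the semaphorin gene Sema6d (2.50 ± 0.42) and Gas6, a bridging ligand in the uptake of dying cells (2.05 ± 0.35), rose, and Klra9, of the Ly49 receptor family of NK cells (-3.20 ± 0.55), and the lymphocyte GTPase gene Gimap3 (-2.69 ± 0.42) fell. These 5 missed the threshold without ND replicate 1, and also without ND replicate 2 for Gas6 and Klra9 and without HFD replicate 2 or 3 for Gpnmb, with adjusted p up to 0.40, 0.074, 0.064, 0.074 and 0.098 in the order named. The rise of Sema6d was at least 2.21, with no ND array above its median. Ctsk was above it on 1 of 2 ND arrays, and Akr1c18 on 1 of 3 HFD arrays. Zbtb46, Ccr7 and H2-Ab1 did not pass: the transcription factor gene Zbtb46 differed by 0.74 ± 0.24 (adjusted p = 0.29), the lymph node homing receptor gene Ccr7 by 0.56 ± 0.51 (adjusted p = 0.90) and the MHC class II gene H2-Ab1 by -0.07 ± 0.67 (adjusted p = 1).

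Of 21 lipid-associated macrophage genes 3 rose in HFD ATDC, namely Ctsk, Gpnmb and the cathepsin gene Ctsl at 1.82 (9 adjusted over the list alone). The lipid-associated macrophage list had a camera adjusted p = 8.08e-11, or adjusted p = 0.157 with an estimated correlation. That count was 1 without ND replicate 1, HFD replicate 2 or HFD replicate 3, each of which ended the calls of Gpnmb and Ctsl (adjusted p up to 0.40 and 0.32). No gene of 10 in the B cell list passed (4 lower adjusted over the list alone), and the list was called lower as a set (median -0.802), with Bank1 at -1.87 and Cd79a at -1.52, and 1 gene lower without HFD replicate 2. The B cell list had a camera adjusted p = 1.62e-05, or adjusted p = 0.0254 with an estimated correlation. No gene of 11 in the NK cell and innate lymphoid cell list passed (4 lower adjusted over the list alone), but 2 passed without HFD replicate 1 and 1 without ND replicate 2. The NK cell list had a camera adjusted p = 1.1e-05, or adjusted p = 0.118 with an estimated correlation. This list stood at 7.04 and 7.31 on the ND ATDC arrays and at 6.92, 4.59 and 4.94 on the HFD ATDC arrays, so that HFD replicate 1 lay near the ND arrays. The T cell list had a mean level of 5.74 in ND and 4.75 in HFD ATDC, and the dissociation stress list of 8.03 and 7.40. No gene of 18 in the dendritic cell identity list passed (1 lower adjusted over the list alone, 1 lower without ND replicate 2 or HFD replicate 2, median -0.044, camera adjusted p = 0.996). The count of 40 was 81 without ND replicate 2, 78 without HFD replicate 1 and 18 without HFD replicate 3. It was 96 without the 3 arrays that stood apart, of which HFD ATDC replicate 1 is in this comparison, and 0 in a limma fit of these 5 arrays alone, beside 1335 genes at an unadjusted p under 0.05 in the fit of all arrays.

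In PA, HFD against ND (3 against 3 arrays) changed 401 genes in limma (262 higher, 139 lower), and 135 of them (83 higher, 52 lower) passed with each of the 6 arrays left out. Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, rose by 5.23 ± 0.60 (adjusted p = 6.1e-05, above the array median on 1 of 3 ND arrays), and Mmp3 (stromelysin) by 4.99 ± 0.77. The collagen gene Col8a1 rose by 4.72 ± 0.62 and the protease inhibitor gene Timp1 by 3.91 ± 0.58. Genes of myeloid cells rose as well, among them the lipid receptor gene Trem2 (3.74 ± 0.67, adjusted p = 0.0035), the chemokine gene Ccl8 (3.69 ± 0.69) and the inhibitory receptor gene Lilrb4a (3.65 ± 0.67). So did Mmp12 (3.56 ± 0.45), the lectin gene Clec12a (3.49 ± 0.56) and Adgre1 (2.98 ± 0.54, adjusted p = 0.004). Nt5e, the ectoenzyme CD73, fell by 3.64 ± 0.24 (adjusted p = 2.7e-08), and the Wnt agonist gene Rspo3 by 3.58 ± 0.47. The ADP receptor gene P2ry1 fell by 3.08 ± 0.45, the prokineticin receptor gene Prokr1 by 2.81 ± 0.40 and Pappa, a protease that frees insulin-like growth factors, by 2.58 ± 0.26. All of these passed in every leave-out, and the largest rises and falls separated the diets on all 6 arrays. Mrc1 (2.83 ± 0.55, adjusted p = 0.006) missed the threshold without ND replicate 3 or HFD replicate 3 (adjusted p up to 0.054). Pdgfra (-0.38 ± 0.73), Pparg (0.18 ± 0.26), Adipoq (0.49 ± 0.31) and Col1a1 (1.88 ± 0.54) did not pass (adjusted p = 0.95, 0.92, 0.65 and 0.07).

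Macrophage markers moved with diet in the PA sort. Of 15 macrophage identity genes 8 rose (10 adjusted over the list alone), led by Adgre1, Cd68 (2.94), Mrc1 and C1qb (2.58). This list had a camera adjusted p = 2.1e-12, or adjusted p = 0.111 with an estimated correlation. The list stood at 7.07, 6.21 and 8.08 on the HFD arrays and at 5.60, 4.96 and 4.20 on the ND arrays, and the count was 4 without HFD replicate 3 or ND replicate 3 and 5 without HFD replicate 1 or ND replicate 2. Of 21 lipid-associated macrophage genes 11 rose (13 adjusted over the list alone), with 5 passing without HFD replicate 3 and 7 without ND replicate 2 or 3. The list had a camera adjusted p = 2.52e-19, or adjusted p = 0.056 with an estimated correlation. Of 15 complement genes 7 rose, led by C4b at 3.06 (8 adjusted over the list alone, 4 without ND replicate 2, ND replicate 3 or HFD replicate 3). The complement list had a camera adjusted p = 5.02e-10, or adjusted p = 0.056 with an estimated correlation. The endothelial cell list stood at 4.67, 4.81 and 4.75 on the HFD arrays and at 4.38, 3.27 and 3.20 on the ND arrays, and the MHC class II and antigen presentation list at 7.31 on ND replicate 1 against 4.95 and 5.04 on the other ND arrays.

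Of 36 fibrillar collagen and extracellular matrix genes 5 rose in HFD PA (8 higher and 1 lower adjusted over the list alone), with Col8a1 and the matrix glycoprotein gene Tnc (3.17) at the top. The collagen list had a camera adjusted p = 3.57e-10, or adjusted p = 0.269 with an estimated correlation. That count was 2 without ND replicate 2, ND replicate 3 or HFD replicate 3 and 3 without HFD replicate 2. Of 19 TGF-beta and myofibroblast genes 5 rose, among them the contractile protein gene Tagln (2.26) and the latent TGF-beta binding protein gene Ltbp2 (1.84), which passed in every leave-out (5 adjusted over the list alone). The TGF-beta list had a camera adjusted p = 7.95e-06, or adjusted p = 0.056 with an estimated correlation. The count was 3 without ND replicate 2 or HFD replicate 3 and 2 without ND replicate 3. No ND array was above its median for Tnc and Ltbp2, whose rises were at least 2.66 and 1.49. Of 39 cell cycle genes 7 rose, led by the cyclin gene Ccnb2 at 2.51 (17 adjusted over the list alone), and 1 passed without ND replicate 2, ND replicate 3, HFD replicate 2 or HFD replicate 3. The list had a camera adjusted p = 5.12e-13, or adjusted p = 0.17 with an estimated correlation. No gene of the preadipocyte and fibroblast identity list passed (1 higher adjusted over the list alone, median 0.253, 1 without ND replicate 1). The preadipocyte list had a camera adjusted p = 0.0416, or adjusted p = 0.64 with an estimated correlation. The count of 401 was 206 without ND replicate 2, 191 without ND replicate 3, 262 without HFD replicate 1 and 177 without HFD replicate 3. It was 180 in a fit of these 6 arrays alone and 1119 with array weights. Postn was the 1 gene higher in HFD in all 3 cell types (4.75 in CD11c- ATM, 2.61 in ATDC, 2.17 in PA), although its call was lost without any 1 of the ATDC arrays (adjusted p up to 0.24) and without ND replicate 2, ND replicate 3, HFD replicate 2 or HFD replicate 3 of PA (up to 0.079). Of the genes higher in HFD, 12 were shared by CD11c- ATM and PA, against 1.1 for independent lists, while 0 of the lower genes were, against 0.2. Abundant preadipocyte genes were higher in the HFD CD11c- ATM sort (median 1.19) and abundant macrophage genes in the HFD PA sort (median 1.47). Independent lists leave out such RNA of other cells. Its part in this overlap and in the Postn rises was not tested. ATDC and PA shared 1 higher and 0 lower genes, against 0.4 and 0.1, and CD11c- ATM and ATDC shared 3 higher genes, against 0.1, and 1 lower gene. The interaction test found 9 genes whose HFD effect differed between ATDC and CD11c- ATM (7 with a higher and 2 with a lower value in ATDC), among them Mmp9 at 3.44 ± 0.50 (adjusted p = 0.011), which missed the threshold without either ND CD11c- ATM array (up to 0.058). Of the 9 genes 1 passed in every leave-out, Slc7a13 at 2.59, which was named after its values were seen. The count of 9 was 1 without ND CD11c- ATM replicate 1, 4 without ND CD11c- ATM replicate 2 or HFD CD11c- ATM replicate 1, and 2 without HFD CD11c- ATM replicate 3. It was 15 without ND ATDC replicate 2 and 5 without HFD ATDC replicate 1 or 3.

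The 2 macrophage subsets of HFD mice were compared to ask how CD11c+ and CD11c- ATM differed in obesity (3 against 3 arrays). A single gene passed in limma, against 997 at an unadjusted p under 0.05: Klrb1b, a lectin-like NK receptor, was higher in CD11c+ ATM by 2.49 ± 0.37 (adjusted p = 0.032), or at least 1.86, as no CD11c- array was above its median. It lost its call without CD11c+ replicate 1 or 2 or CD11c- replicate 1 or 3 (adjusted p up to 0.13). Itgax itself was higher by 2.40 ± 0.60 without passing (adjusted p = 0.34), and the resident macrophage gene Lyve1 stood at -2.07 ± 0.62 (adjusted p = 0.43). Gpnmb (1.30 ± 0.62), Cd9 (1.12 ± 0.43), Adgre1 (0.18 ± 0.54) and H2-Ab1 (-0.10 ± 0.60) did not pass either.

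Camera called lists of which no single gene passed. Of 20 tissue-resident macrophage genes none passed (7 lower adjusted over the list alone), with Cd209g at -2.68 and Cd209d at -2.47. This list had a median of -1.10 and a camera adjusted p = 3.89e-12, or adjusted p = 0.205 with an estimated correlation. The lipid-associated macrophage list was called higher (4 of 21 higher adjusted over the list alone). It had a median of 0.522 and a camera adjusted p = 1.39e-07, or adjusted p = 0.219 with an estimated correlation. The cell cycle list was called higher too (0 of 39 adjusted over the list alone). It had a median of 0.816 and a camera adjusted p = 1.57e-18, or adjusted p = 0.13 with an estimated correlation. The fibrillar collagen and extracellular matrix list was called lower in CD11c+ ATM (12 of 36 lower adjusted over the list alone), and its median was -0.45 without CD11c- ATM replicate 3, the array with the highest preadipocyte marker level. The collagen list had a median of -1.20 and a camera adjusted p = 1.29e-27, or adjusted p = 0.125 with an estimated correlation. The monocyte list (2 of 12 lower adjusted over the list alone) stood at 6.51, 6.22 and 5.83 on the CD11c+ arrays against 6.74, 6.89 and 7.17 on the CD11c- arrays, with a camera adjusted p = 0.00022, or adjusted p = 0.125 with an estimated correlation. The dissociation stress list (0 of 28 adjusted over the list alone) stood at 7.11, 7.52 and 7.33 against 7.92, 7.91 and 7.97, with a camera adjusted p = 0.0022, or adjusted p = 0.445 with an estimated correlation. The count of 1 was 0 without CD11c+ replicate 1 or CD11c- replicate 1, and 3 without CD11c- replicate 2. It was 26 with array weights, 2 without the 3 arrays that stood apart, and 0 in a limma fit of these 6 arrays alone. In data simulated on this comparison, 94% of genes changed by 2 log2 units and 26.9% of genes changed by 1 unit were called. That simulation held more changed genes than were called here, which loosens the adjusted threshold. It therefore does not show that differences of 2 units were absent.

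Weight loss was examined first in CD11c+ ATM (WL against HFD, 3 against 3 arrays). The cytokine gene Il6 rose by 4.18 ± 0.50 (adjusted p = 0.00063), the ubiquitin hydrolase gene Uchl1 by 4.10 ± 0.67, and the matricellular protein gene Ccn1 by 3.97 ± 0.64. The eosinophil-attracting chemokine gene Ccl11 rose by 3.40 ± 0.41, the microtubule protein gene Map1b by 3.38 ± 0.56 and the protease inhibitor gene Serpinb9b by 3.30 ± 0.52 (adjusted p = 0.0078). Tmem171 fell by 2.87 ± 0.49, the palmitoyltransferase gene Zdhhc23 by 2.68 ± 0.41 and Adgre4, a relative of F4/80, by 2.55 ± 0.40 (adjusted p = 0.0078). These 9 genes separated the groups on all 6 arrays and passed in every leave-out. The preadipocyte list rose too, and preadipocyte RNA as a source of the rises was not tested. No HFD array was above its median for Il6, which rose by at least 3.07, and no WL array for Zdhhc23, at least 2.02 lower. The cytokine gene Il1b rose by 1.89 ± 0.37 (adjusted p = 0.02), and its call was lost without any 1 of the HFD arrays (adjusted p up to 0.10). The costimulatory gene Cd86 fell by 1.17 ± 0.27 (adjusted p = 0.04), and its call was lost without any 1 of the HFD arrays, WL replicate 1 or WL replicate 2 (up to 0.15). Itgax (0.29 ± 0.60), Trem2 (-0.21 ± 0.67), Cd9 (-0.21 ± 0.43), Gpnmb (0.48 ± 0.62) and Tnf (0.90 ± 0.37) did not pass (adjusted p = 0.82, 0.89, 0.82, 0.71 and 0.19).

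Of 36 fibrillar collagen and extracellular matrix genes 6 rose in WL CD11c+ ATM (22 adjusted over the list alone), among them the proteoglycan genes Bgn (2.11, adjusted p up to 0.14 over the leave-outs) and Lum (1.90, up to 0.16). The count was 0 without HFD replicate 2, HFD replicate 3 or WL replicate 2, 1 without WL replicate 1 and 19 without the 3 arrays that stood apart. The collagen list had a median of 1.34 and a camera adjusted p = 4.58e-18, or adjusted p = 0.127 with an estimated correlation. Of 18 preadipocyte and fibroblast identity genes, 6 of them also in that list, 2 rose (11 adjusted over the list alone). This count was 0 without HFD replicate 2, HFD replicate 3, WL replicate 1 or WL replicate 2, 4 without WL replicate 3 and 7 without the 3 arrays that stood apart. The preadipocyte list had a median of 1.33 and a camera adjusted p = 3.04e-08, or adjusted p = 0.127 with an estimated correlation. It stood at 7.97, 8.38 and 7.71 on the WL arrays and at 7.46, 6.55 and 6.35 on the HFD arrays. Of 9 neutrophil genes 2 rose (3 adjusted over the list alone), 0 without HFD replicate 2 or 3 and 1 without HFD replicate 1, WL replicate 1 or WL replicate 2. The neutrophil list had a camera adjusted p = 0.00263, or adjusted p = 0.0822 with an estimated correlation. Of 22 proinflammatory cytokine and chemokine genes 3 rose, namely Il6, Il1b and the prostaglandin synthase gene Ptgs2 at 2.63, whose adjusted p reached 0.16 in leave-outs (3 adjusted over the list alone, 1 without any 1 of the HFD arrays). The proinflammatory list had a camera adjusted p = 5.86e-05, or adjusted p = 0.127 with an estimated correlation. Of 28 dissociation stress and immediate early genes 1 rose, Socs3 at 1.48 (2 adjusted over the list alone, 0 without HFD replicate 2 or 3, 2 without WL replicate 1). This list had a median of 0.323 and a camera adjusted p = 4.8e-05, or adjusted p = 0.363 with an estimated correlation. It stood at 7.66, 8.67 and 8.36 on the WL arrays and at 7.11, 7.52 and 7.33 on the HFD arrays. Of 20 NRF2 and oxidative stress genes 3 rose, led by the cystine transporter gene Slc7a11 at 2.97 (at least 2.35, with no HFD array above its median), whose adjusted p reached 0.13 in leave-outs (9 adjusted over the list alone), with 1 passing without HFD replicate 1 and 0 without HFD replicate 2 or 3. The NRF2 list had a camera adjusted p = 7.42e-09, or adjusted p = 0.0822 with an estimated correlation. No gene of the 24 of the interferon response list passed (9 lower adjusted over the list alone, 2 without WL replicate 3), with Oas2 at -1.82. The interferon list had a median of -0.595 and a camera adjusted p = 3.2e-05, or adjusted p = 0.0822 with an estimated correlation.

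In WL CD11c+ ATM 206 genes passed in limma (98 higher, 108 lower), 19 of them (12 higher, 7 lower) in every leave-out. The median of all genes was -0.101 here and 0.023 after cyclic loess normalization, which called 193 genes (147 higher, 46 lower), so the share of calls that were higher moved from 47.6% to 76.2%. The count was 79 without HFD replicate 1, 34 without HFD replicate 2, and 23 without HFD replicate 3. It was 115 without WL replicate 1, 124 without WL replicate 2, 771 without WL replicate 3, and 4 in a fit of these 6 arrays alone.

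In CD11c- ATM (2 WL against 3 HFD arrays), mast cell genes and inflammatory and immediate early genes were higher on the WL arrays. Tph1, the serotonin-synthesis enzyme of mast cells and other peripheral cells, rose by 5.20 ± 0.27 (adjusted p = 7.9e-10), the IgE receptor gene Fcer1a by 5.25 ± 0.65, and the receptor genes Mrgprb1 and Mrgprb2 by 5.13 ± 0.49 and 4.85 ± 0.59. The tryptase gene Tpsab1 rose by 5.08 ± 0.40, the histamine-forming enzyme gene Hdc by 4.63 ± 0.41, and Kit, the stem cell factor receptor, by 4.06 ± 0.48. No HFD array was above its median for Tph1, Tpsab1 and Hdc, whose rises were at least 4.44, 4.52 and 4.00, and 1 of 3 was for Fcer1a, Mrgprb1 and Mrgprb2. Il6 rose by 5.96 ± 0.56 (adjusted p = 2.9e-06, above the median on 1 of 3 HFD arrays), Il1b by 3.40 ± 0.42 (adjusted p = 1e-04), and the granzyme gene Gzmb, a member of the NK cell list, by 4.54 ± 0.57. The transcription factor genes Egr3 and Nr4a1 rose by 3.81 ± 0.71 and 3.68 ± 0.56. Mmp9 rose by 2.28 ± 0.35 (adjusted p = 0.0015), and remained below ND (-2.51 ± 0.39 in WL against ND, adjusted p = 0.00078). Rad1, a subunit of the DNA damage clamp, fell by 3.45 ± 0.36 (adjusted p = 1.1e-05) and the noncoding RNA gene Rab26os by 2.76 ± 0.45. All of these passed in every leave-out, and the largest rises and falls separated both WL from all 3 HFD arrays. Itgax (0.39 ± 0.67), Gpnmb (0.80 ± 0.70), Cd9 (-0.08 ± 0.48), Col3a1 (0.35 ± 0.54), Mrc1 (-0.30 ± 0.61) and Tnf (1.40 ± 0.41) did not pass (adjusted p = 0.83, 0.60, 0.96, 0.80, 0.86 and 0.072).

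**Figure D3:**
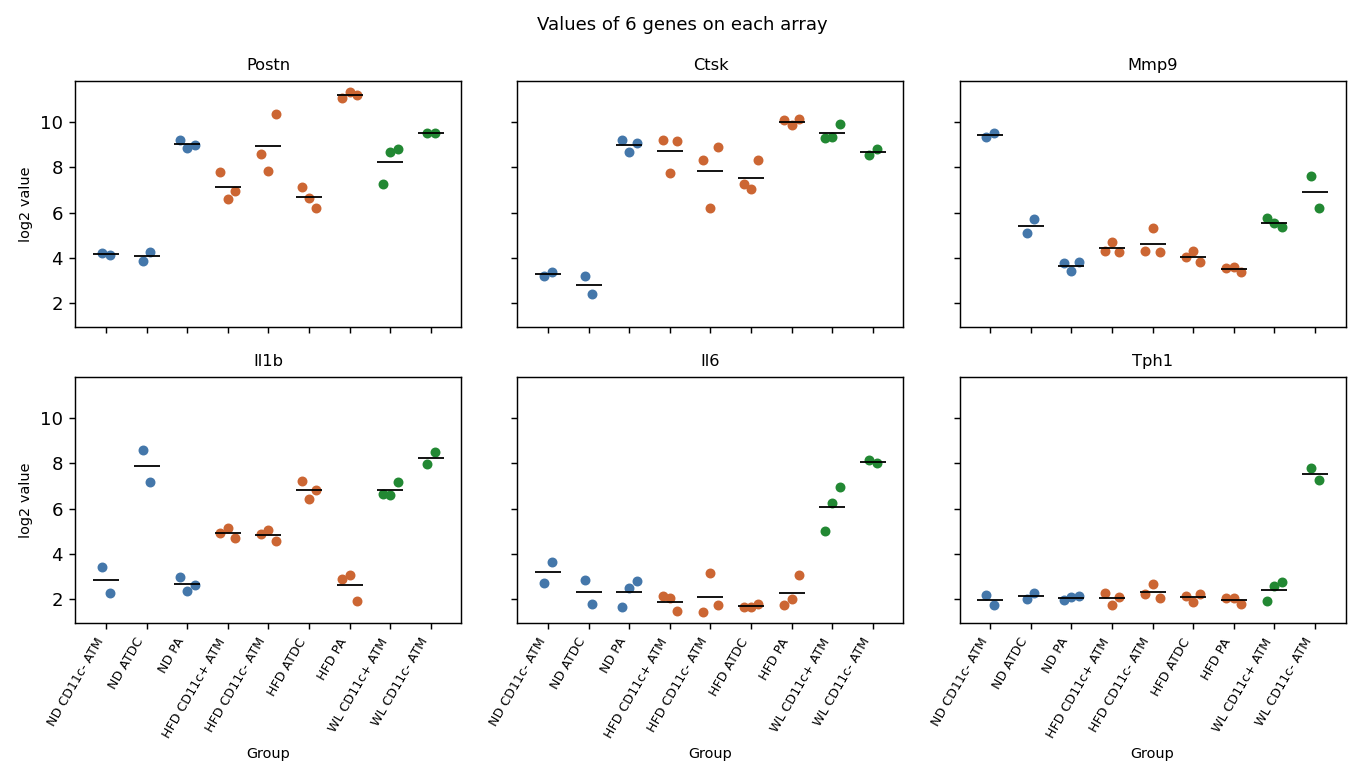
Log2 values (vertical axis) of 6 genes on each array (points) in the 9 groups (horizontal axis), with the group mean as a black line; blue is ND, orange HFD and green WL. Tph1 averages 7.52 in WL CD11c- ATM and 2.42 in WL CD11c+ ATM, Il6 averages 8.07 in WL and 2.11 in HFD CD11c- ATM, and Mmp9 averages 9.42 in ND and 4.62 in HFD CD11c- ATM.

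Of 11 mast cell and eosinophil genes 6 rose (8 adjusted over the list alone). The mast cell list had a median of 4.06 and a camera adjusted p = 6.61e-12, or adjusted p = 0.0352 with an estimated correlation. The list stood at 7.22 and 8.43 on the WL CD11c- arrays, at 4.73, 3.36 and 3.78 on the WL CD11c+ arrays, and at 4.31, 2.35 and 3.02 on the HFD CD11c- arrays. Of 22 proinflammatory cytokine and chemokine genes 4 rose and 1 fell (7 and 1 adjusted over the list alone), with 2 rises without HFD replicate 2 and no fall without HFD replicate 2 or WL replicate 2. The list had a camera adjusted p = 2.02e-07, or adjusted p = 0.041 with an estimated correlation. Of 28 dissociation stress and immediate early genes 7 rose, led by Egr3, Nr4a1, Nr4a2 (3.13, adjusted p = 0.13 without WL replicate 2, above the median on 1 of 3 HFD arrays) and Fosl2 (2.09) (10 adjusted over the list alone), and 4 passed without HFD replicate 2 or either WL array. This list had a camera adjusted p = 4.36e-11, or adjusted p = 0.0739 with an estimated correlation. That list stood at 9.21 and 9.11 on the WL arrays, at 7.92, 7.91 and 7.97 on the HFD arrays and at 8.48 and 8.39 on the ND CD11c- arrays. Of 12 endothelial cell genes 3 rose, led by Plvap at 2.34 (8 adjusted over the list alone, 1 without HFD replicate 1 or WL replicate 2). The endothelial list had a camera adjusted p = 5.1e-08, or adjusted p = 0.041 with an estimated correlation. Of 11 NK cell and innate lymphoid cell genes 2 rose, Gzmb and Klrb1c, the latter not without WL replicate 2 (3 adjusted over the list alone). This list stood at 5.09 and 4.90 on the WL arrays against 3.95, 3.79 and 3.80 on the HFD arrays, with a median of 1.45 and a camera adjusted p = 1.25e-05, or adjusted p = 0.0529 with an estimated correlation. Of 12 monocyte genes 1 rose, Nr4a1, also a member of the dissociation stress list (1 adjusted over the list alone, 2 without HFD replicate 3). The monocyte list stood at 8.07 and 7.46 on the WL arrays against 6.74, 6.89 and 7.17 on the HFD arrays, with a camera adjusted p = 0.0121, or adjusted p = 0.176 with an estimated correlation. Of 24 interferon response genes 2 fell, Stat2 (-1.62, adjusted p up to 0.078 over the leave-outs) and Ifih1 (-0.84, up to 0.21) (6 adjusted over the list alone), with 0 passing without HFD replicate 1 and 1 without HFD replicate 2, HFD replicate 3 or WL replicate 2. The interferon list had a camera adjusted p = 0.00125, or adjusted p = 0.0954 with an estimated correlation. Of 21 lipid-associated macrophage genes none passed (1 higher adjusted over the list alone, 1 without HFD replicate 3, median 0.174, camera adjusted p = 0.0529). Of 36 fibrillar collagen and extracellular matrix genes 1 rose, and 11 rose without HFD replicate 3, the array on which this list stood highest among the HFD macrophage arrays. From HFD to WL, mean levels went from 4.16 to 5.17 for the B cell list and from 3.18 to 3.99 for the mesothelial list. They went from 3.46 to 3.60 for the neutrophil, 4.38 to 5.12 for the adipogenesis and 7.80 to 8.73 for the preadipocyte list. The macrophage identity list went from 9.65 to 9.25.

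In this comparison 459 genes passed in limma (182 higher, 277 lower), and 74 (47 higher, 27 lower) passed in every leave-out. After cyclic loess normalization 318 passed (197 higher, 121 lower), so the share of calls that were higher moved from 39.7% to 61.9%. The count was 199 without HFD replicate 1, and 277 without HFD replicate 2. It was 31 in a fit of these 5 arrays alone, 173 with array weights and 808 without the 3 arrays that stood apart. Across the 15496 genes, the WL minus HFD differences of the subsets correlated with r = 0.49. Against 1.2 and 1.9 for independent lists, 23 genes rose in both subsets, Il6 and Il1b among them, and 19 fell in both. Independent lists leave out a WL batch and RNA of other cells, whose part in this overlap was not tested. The interaction test found 25 genes whose WL effect differed between the subsets (3 with a higher and 22 with a lower signed value in CD11c+ ATM), among them Tph1 at -4.82 ± 0.36 (adjusted p = 6.1e-07). Of the 25 genes 11 passed in every leave-out, Tph1 among them and all of them lower. The size of this Tph1 term is not exact, as no array was above its median in 3 of the 4 groups. The interaction count was 12 without HFD CD11c+ replicate 1, HFD CD11c+ replicate 2 or HFD CD11c- replicate 2, 13 without HFD CD11c- replicate 3, and 15 without HFD CD11c+ replicate 3. It was 16 without WL CD11c+ replicate 3, 52 without WL CD11c- replicate 1 and 63 without WL CD11c- replicate 2, and 7 in a fit of these 11 arrays alone.

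WL was then set against ND in CD11c- ATM (2 against 2 arrays), to ask what still differed from lean mice after weight loss. Mast cell protease genes were among those that rose most, with Tpsb2 at 8.55 ± 1.22 (adjusted p = 0.00036), the carboxypeptidase gene Cpa3 at 7.73 ± 1.51 (adjusted p = 0.0044) and the chymase gene Cma1 at 5.97 ± 1.14. Macrophage and matrix genes that were higher in HFD were higher after weight loss too: Mmp12 by 5.66 ± 0.55 (adjusted p = 3.4e-06), Ctsk by 5.40 ± 0.63 and Postn by 5.31 ± 0.59. Gpnmb was higher by 4.46 ± 0.76, Col3a1 by 3.88 ± 0.59 and Cd9 by 2.82 ± 0.53 (adjusted p = 0.0034). Il1b was higher by 5.38 ± 0.46 (adjusted p = 9.5e-07), Il6 by 4.89 ± 0.61 and the neutrophil-attracting chemokine gene Cxcl1 by 4.67 ± 0.88. Slc7a13 was lower by -3.49 ± 0.22 (adjusted p = 1.8e-08), and Tnfrsf17, the B cell maturation antigen, by -3.77 ± 0.52. The DNase gene Dnase1l3 was lower by -3.54 ± 0.56 and Pla2g2d by -3.05 ± 0.58. All of these passed with each of the 4 arrays left out. No ND array was above its median for Tpsb2, Cpa3 and Itgax, with differences of at least 7.18, 7.59 and 3.41, and no WL array for Slc7a13, at least 2.85 lower. Il1b was above it on 1 of 2 ND arrays and Dnase1l3 on 1 of 2 WL arrays. Itgax (3.63 ± 0.73, adjusted p = 0.0052) missed the threshold without WL replicate 2 (adjusted p up to 0.052), and Lpl (1.57 ± 0.31, adjusted p = 0.0051) without ND replicate 1 (up to 0.056). Pdgfra (4.12 ± 0.90, adjusted p = 0.0088) missed it without ND replicate 2 or WL replicate 1 (up to 0.083), and Tnf (1.95 ± 0.45, adjusted p = 0.013) without ND replicate 1 or WL replicate 2 (up to 0.17). Adgre1 (-0.23 ± 0.67) and Lyve1 (-1.52 ± 0.76) did not pass (adjusted p = 0.92 and 0.28).

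Of 36 fibrillar collagen and extracellular matrix genes 23 rose (31 adjusted over the list alone), with 15 without ND replicate 1, 11 without ND replicate 2 and 13 without WL replicate 1. The collagen list had a median of 2.55 and a camera adjusted p = 2.58e-30, or adjusted p = 0.0405 with an estimated correlation. Of 21 matrix remodelling genes 13 rose and 1, Mmp9, fell (16 and 1 adjusted over the list alone, 8 rises without ND replicate 1). This list had a camera adjusted p = 1.74e-14, or adjusted p = 0.035 with an estimated correlation. Of 18 preadipocyte and fibroblast identity genes 11 rose (13 adjusted over the list alone, 5 without ND replicate 2), and the list stood at 9.04 and 8.42 on the WL arrays against 6.20 and 5.89 on the ND arrays. The preadipocyte list had a camera adjusted p = 1.37e-14, or adjusted p = 0.0405 with an estimated correlation. Of 21 lipid-associated macrophage genes 10 rose (12 adjusted over the list alone, 5 without ND replicate 1 or WL replicate 2). The list had a camera adjusted p = 3.08e-11, or adjusted p = 0.0671 with an estimated correlation. Of 11 mast cell and eosinophil genes 8 rose (8 adjusted over the list alone). The mast cell list had a camera adjusted p = 1.23e-13, or adjusted p = 0.035 with an estimated correlation. Of 12 monocyte genes 4 rose (8 adjusted over the list alone, 2 without WL replicate 1), and of 11 NK cell genes 2 rose (5 adjusted over the list alone, 1 without ND replicate 1 or WL replicate 1). The monocyte list had a camera adjusted p = 2.19e-06, or adjusted p = 0.035 with an estimated correlation, and the NK cell list a camera adjusted p = 2.5e-05, or adjusted p = 0.062. Of 28 dissociation stress and immediate early genes 5 rose and 1 fell (7 and 1 adjusted over the list alone), with no fall in any leave-out and 3 rises without ND replicate 2. This list had a camera adjusted p = 5.12e-05, or adjusted p = 0.258 with an estimated correlation. Of 22 proinflammatory cytokine and chemokine genes 6 rose and 1 fell (9 and 1 adjusted over the list alone, no fall without ND replicate 2 or WL replicate 2). The list had a camera adjusted p = 5.91e-07, or adjusted p = 0.0475 with an estimated correlation. Of 24 interferon response genes 5 fell, led by Oas2 at -1.99, whose adjusted p reached 0.21 in leave-outs (1 higher and 6 lower adjusted over the list alone), with 0 without ND replicate 1, 1 without ND replicate 2, 3 without WL replicate 1 and 2 without WL replicate 2. The interferon list had a camera adjusted p = 0.00563, or adjusted p = 0.132 with an estimated correlation. For the lysosome list (median -0.077, camera adjusted p = 0.697), the complement list (median -0.128, camera adjusted p = 0.0458, adjusted p = 0.417 with an estimated correlation) and the dendritic cell identity list (median -0.176, camera adjusted p = 0.823) the median was negative while the test pointed up.

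This comparison had 957 genes past the threshold in limma (500 higher, 457 lower), of which 193 (133 higher, 60 lower) passed in every leave-out. Cyclic loess normalization called 909 (583 higher, 326 lower), so the share of calls that were higher moved from 52.2% to 64.1%. The count was 400 without ND replicate 1, 374 without ND replicate 2, 222 in a fit of these 4 arrays alone and 594 with array weights. Of the 68 genes higher and 27 lower in HFD CD11c- ATM, 59 and 23 passed in WL against ND as well. The median HFD minus ND difference of the 68 genes was 2.58 and their median WL minus ND difference 3.16, and for the 27 genes these were -1.89 and -1.76. Genes chosen against the same 2 ND arrays tend to stay on their side of ND with no effect at all. In 100 draws of unchanged groups against those arrays, the 68 and 27 genes of smallest p had mean medians of 1.05 and -1.18 in HFD and 0.63 and -0.71 in WL. Of them, 95.7% and 96.7% were on the same side of ND in WL, against 98.5% and 100% measured. Another 100 draws kept the HFD difference and set WL at the ND mean. There the genes called, on average 380 higher and 213 lower, were on the same side of ND in WL in 71.1% and 77%. Their mean median WL minus ND differences were 0.25 and -0.28. Past the threshold in WL against HFD, 3 of the 68 were lower and 1 of the 27 was higher. In the same comparisons, 181 genes outside the matrix lists that were abundant in ND PA, with a log2 level over 8 and at least 3 units above HFD CD11c+ ATM and ND ATDC, had a median difference of 1.19 in HFD and 2.21 in WL against ND CD11c- ATM. Both comparisons used the same 2 ND arrays, so part of this overlap may come from those shared controls. Unchanged groups that shared simulated ND arrays had at most 1 call per comparison in 100 draws, so that the 0 genes they shared give no measure of that part. Independent lists, which leave out the shared arrays, would share 2.2 and 0.8. The covariance of the log2 differences across genes was 0.275 against 0.103 simulated (r = 0.61 against 0.55). The number shared, 82, was 26 without ND replicate 1, 32 without ND replicate 2, 27 without HFD replicate 3 and 135 without HFD replicate 2.

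After weight loss the 2 macrophage subsets differed in 208 genes in limma (107 higher and 101 lower in CD11c+ ATM, 3 against 2 arrays), and 42 (9 higher, 33 lower) passed in every leave-out. Genes of mast cells were lower in CD11c+ ATM, with Tph1 at -5.09 ± 0.27 (adjusted p = 1.2e-09), Fcer1a at -4.88 ± 0.65, Tpsab1 at -4.49 ± 0.40, Mrgprb2 at -4.47 ± 0.59 and Mrgprb1 at -4.24 ± 0.49. Rad1 (2.52 ± 0.36, adjusted p = 0.0011) and the tRNA-modifying enzyme gene Trit1 (2.30 ± 0.36, adjusted p = 0.0024) were higher. These 7 genes separated the subsets on all 5 arrays and passed in every leave-out, although Rad1 did not pass when its probe rows were averaged. The dendritic cell chemokine gene Ccl22 was higher by 4.02 ± 0.85 (adjusted p = 0.024), and missed the threshold without CD11c+ replicate 2 or either CD11c- array (up to 0.09). No CD11c+ array was above its median for Tph1 (at least 4.46 lower) and 2 of 3 were for Mrgprb2, and no CD11c- array was for Ccl22 (at least 3.14 higher). Itgax was higher by 2.30 ± 0.67 and Il1b lower at -1.43 ± 0.42 without passing (adjusted p = 0.092 and 0.096). Of 11 mast cell and eosinophil genes 4 were lower (6 adjusted over the list alone). The mast cell list had a camera adjusted p = 3.45e-10, or adjusted p = 0.0402 with an estimated correlation. Of 12 monocyte genes 2 were lower, Ms4a4c (-3.30) and Chil3 (-2.54, adjusted p up to 0.18 over the leave-outs) (5 adjusted over the list alone, 1 without CD11c+ replicate 3 or either CD11c- array). The monocyte list had a camera adjusted p = 4.98e-06, or adjusted p = 0.0386 with an estimated correlation. Of 10 B cell genes 1 was lower, Ms4a1 at -1.76, with adjusted p = 0.057 without CD11c- replicate 2 (1 higher and 4 lower adjusted over the list alone). The B cell list had a camera adjusted p = 0.000147, or adjusted p = 0.0386 with an estimated correlation. No CD11c+ array was above its median for Chil3 and Ms4a1, at least 2.05 and 0.98 lower. Of 11 NK cell genes 1 was lower, Gzmb (2 adjusted over the list alone), and of 28 dissociation stress and immediate early genes 2 were (10 adjusted over the list alone, 1 without CD11c+ replicate 2). The NK cell list had a camera adjusted p = 0.000216, or adjusted p = 0.191 with an estimated correlation, and the dissociation stress list a camera adjusted p = 3.95e-07, or adjusted p = 0.282. The count of 208 was 43 with array weights, 1 in a fit of these 5 arrays alone and 405 without the 3 arrays that stood apart.

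ATDC and CD11c+ ATM both carry CD11c, and were compared within HFD mice (3 against 3 arrays). Dendritic cell genes were higher in ATDC: Xcr1, a chemokine receptor of cross-presenting dendritic cells, by 4.43 ± 0.46 (adjusted p = 6.4e-06), and the inhibitory receptor gene Btla by 4.23 ± 0.39. Ccr7 was higher by 4.10 ± 0.46, Zbtb46 by 2.28 ± 0.22 (adjusted p = 3.2e-06) and the cytokine gene Il12b by 2.79 ± 0.41. The orphan receptor gene Gpr141b (4.78 ± 0.46), the NK receptor gene Klri1 (4.77 ± 0.28) and Cd7 (4.46 ± 0.45) were higher as well. Macrophage genes were lower, with the complement receptor gene Vsig4 at -3.96 ± 0.77 (adjusted p = 0.0043), the chemokine gene Ccl12 at -3.61 ± 0.75 and the scavenger receptor gene Stab1 at -3.46 ± 0.38. Lower too were the carbonyl reductase gene Cbr2 at -3.28 ± 0.52 and the transporter gene Abcc3 at -3.27 ± 0.45. All of these passed in every leave-out, and the largest rises and falls separated the cell types on all 6 arrays. No CD11c+ array was above its median for Klri1 and Il12b, at least 4.07 and 2.11 higher in ATDC, and 1 of 3 was for Btla. Fcgr1, the Fc receptor CD64, was lower at -3.23 ± 0.68 (adjusted p = 0.0074) and missed the threshold without ATDC replicate 1 (adjusted p up to 0.068). Il10 was lower at -3.03 ± 0.76 (adjusted p = 0.026), and its call was lost without any 1 of the CD11c+ arrays, ATDC replicate 1 or ATDC replicate 2 (up to 0.11). Itgax differed by 0.28 ± 0.60, H2-Ab1 by 0.16 ± 0.60 and Cd86 by 0.89 ± 0.27, none past the threshold (adjusted p = 0.90, 0.95 and 0.075).

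Of 18 dendritic cell identity genes 12 were higher (15 higher and 1 lower adjusted over the list alone). The dendritic cell list had a camera adjusted p = 2.48e-25, or adjusted p = 0.000273 with an estimated correlation. Of 14 costimulation and dendritic cell maturation genes 5 were higher (8 adjusted over the list alone, 3 without ATDC replicate 1). The list had a camera adjusted p = 1.27e-09, or adjusted p = 0.0433 with an estimated correlation. Of 16 MHC class II and antigen presentation genes 4 were higher, led by the accessory chain gene H2-Oa at 4.05 (5 adjusted over the list alone). The MHC class II list had a camera adjusted p = 6.09e-06, or adjusted p = 0.0716 with an estimated correlation. Of 20 tissue-resident macrophage genes 12 were lower (1 higher and 16 lower adjusted over the list alone), with 6 without CD11c+ replicate 1 or ATDC replicate 1 and 7 without CD11c+ replicate 2 or ATDC replicate 3. This list had a camera adjusted p = 3.15e-13, or adjusted p = 0.0988 with an estimated correlation. Of 30 lysosome genes 8 were lower (18 adjusted over the list alone), with 2 without CD11c+ replicate 1 or 3, 3 without CD11c+ replicate 2 and 0 without ATDC replicate 1. The lysosome list had a camera adjusted p = 3.25e-11, or adjusted p = 0.154 with an estimated correlation. Of 13 cholesterol efflux and LXR target genes 4 were lower, led by the transporter gene Abca1 at -2.34 (5 adjusted over the list alone, 2 without ATDC replicate 1). The list had a camera adjusted p = 0.000347, or adjusted p = 0.133 with an estimated correlation. Of 11 NK cell and innate lymphoid cell genes 4 were higher (6 adjusted over the list alone), with 1 without ATDC replicate 1, where the list stood at 6.92, and 2 without CD11c+ replicate 3. The NK cell list had a camera adjusted p = 2.94e-07, or adjusted p = 0.0568 with an estimated correlation. Of 12 monocyte genes 2 were higher (6 higher and 1 lower adjusted over the list alone), 1 without ATDC replicate 1, and 4 higher and 1 lower without ATDC replicate 2. The monocyte list had a camera adjusted p = 0.000755, or adjusted p = 0.0975 with an estimated correlation. The proinflammatory cytokine list had a median of -0.038 while its test pointed up (camera adjusted p = 0.0773). In all 644 genes passed in limma (266 higher, 378 lower), 251 of them (142 higher, 109 lower) in every leave-out. The count was 342 without CD11c+ replicate 1, 354 without CD11c+ replicate 3, and 309 without ATDC replicate 1. It was 392 in a fit of these 6 arrays alone, 1176 with array weights and 357 without the 3 arrays that stood apart.

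Over the 9 comparisons and 2 interactions camera called 165 lists, and 21 of these calls held with an estimated correlation. They were the B cell list in HFD against ND ATDC and the mesothelial, endothelial, B cell, neutrophil, mast cell, proinflammatory and adipogenesis lists in WL against HFD CD11c- ATM. In WL against ND CD11c- ATM they were the preadipocyte, endothelial, monocyte, mast cell, proinflammatory, collagen, matrix remodelling and adipogenesis lists. Between the WL subsets they were the B cell, monocyte and mast cell lists, and between ATDC and CD11c+ ATM the dendritic cell and costimulation lists.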

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

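The tests of a lower share of macrophages or of preadipocytes, of a batch shared by the WL arrays, and of replicate 3 of HFD CD11c- ATM, were chosen only after the results were seen. Each SD below is that of a list's median difference over all pairs of arrays of the groups compared. Such pairs reuse the same arrays and are not independent replicates.

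Interaction tests compared the same diet effect between cell types. The HFD minus ND effect differed between ATDC and CD11c- ATM in 9 genes. Dnase1l3 had an interaction of 4.35 (1.04 in ATDC, -3.31 in CD11c- ATM), Mmp9 of 3.44 (-1.36 and -4.80), and Sema6d of 3.44 (2.50 and -0.94). It was 3.00 for Uaca (2.15 and -0.85) and 2.70 for Tango2 (1.89 and -0.81), while Timp1 had -5.02 (4.02 in CD11c- ATM) and Akr1c18 -3.95 (-3.84 and 0.11). None of these 7 passed in every leave-out. Each missed the threshold without either ND CD11c- ATM array, and all but Mmp9 also without ND ATDC replicate 1, HFD CD11c- ATM replicate 3 or HFD ATDC replicate 1. Other arrays also ended calls: ND ATDC replicate 2 those of Sema6d and Timp1, HFD CD11c- ATM replicate 1 those of Akr1c18, Sema6d, Tango2 and Uaca, and HFD CD11c- ATM replicate 2 those of Tango2, Timp1 and Uaca. HFD ATDC replicate 2 ended those of Sema6d, Tango2 and Uaca, and HFD ATDC replicate 3 those of Akr1c18, Dnase1l3, Tango2 and Timp1. The highest adjusted p was 0.058 for Mmp9, 0.12 for Dnase1l3 and Akr1c18, 0.15 for Sema6d, and 0.25 for Uaca, Tango2 and Timp1. The WL minus HFD effect differed between CD11c+ and CD11c- ATM in 25 genes. Lgi2 had an interaction of 3.02 (2.81 in CD11c+, -0.21 in CD11c- ATM), Rad1 of 2.48 (-0.96 and -3.45) and Gpatch2l of 1.66 (0.12 and -1.54). Tph1 had -4.82 (0.39 and 5.20), Tpsab1 -4.45 (0.63 and 5.08), Gzmb -3.90 (0.63 and 4.54), Mrgprb1 -3.88 (1.26 and 5.13) and Hdc -3.60 (1.03 and 4.63). Tph1, Tpsab1 and Hdc passed in every leave-out, and Mrgprb1 missed the threshold without HFD CD11c+ replicate 1 or HFD CD11c- replicate 2 (up to 0.054). With 1 of the 11 arrays left out, Gzmb passed only where that was WL CD11c- replicate 1 (up to 0.15 otherwise), Rad1 only where it was WL CD11c+ replicate 1 or WL CD11c- replicate 2 (up to 0.14), and Gpatch2l only where it was WL CD11c+ replicate 1 or WL CD11c- replicate 1 (up to 0.13). Lgi2 passed only where it was HFD CD11c- replicate 1, WL CD11c+ replicate 3 or WL CD11c- replicate 1 (up to 0.14). Groups in which no array lay above its own median make these sizes inexact: 3 of the 4 groups for Tph1, 2 for Akr1c18, Tpsab1 and Hdc, and 1 for Sema6d, Lgi2 and Mrgprb1. No group had 4 or more arrays, so single arrays far from the rest of a group were not tested for.

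Mast cell genes were higher in WL than in HFD CD11c- ATM. A lower share of macrophages alone would raise the markers of other cell types alike, but the mast cell list rose by 2.47 log2 units more than the highest other cell type list, with an SD of 1.22. A second mast cell list, of 17 tested genes in no fixed list, had a median change of 1.18 (SD 0.30) against 0.04 for random lists, and 14 of them were above 0, with Cyp11a1 at 4.35 and Slc18a2 at 3.70. Mast cells among the sorted cells may therefore account for these genes, as no gate that would remove them is given in the sources used here, and an effect of diet on mast cells themselves was not tested. The first mast cell list rose by 3.03 more in CD11c- than in CD11c+ ATM (combined SD 1.33). This argues against a batch shared by all WL arrays as the source of the mast cell rise only. Other differences of the WL arrays, such as the rises of Il6 and Il1b in both subsets, were not covered by it. A batch of the WL CD11c- arrays alone cannot be told apart from weight loss.

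Collagen genes were higher in HFD than in ND CD11c- ATM. Replicate 3 of HFD CD11c- ATM alone was argued against as the whole cause, since the median of the collagen list was 1.12 without it (SD 0.27). Abundant preadipocyte genes outside the matrix lists, 181 in number, had a median change of 1.19 (SD 1.01), and 89.5% of them were above 0, so preadipocyte RNA among the sorted macrophages may account for part of the pattern. The same genes had a median change of 2.21 in WL against ND CD11c- ATM. The median per HFD replicate was 0.65, 0.38 and 2.47, and expression of matrix genes by the macrophages stays open, as untested.

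Macrophage genes were higher in HFD than in ND PA. Abundant macrophage genes outside the fixed lists, 126 in number, had a median change of 1.47 (SD 1.03), and 95.2% of them were above 0, so macrophage RNA among the sorted preadipocytes may account for them. Whether a lower share of preadipocytes would do so cannot be told apart from this, because the other cell type lists lay near the floor of the arrays (the macrophage list rose by 1.86 more than the lowest of them). A diet effect on preadipocytes themselves stays open, as untested.

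With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split gave 401 genes and the highest other 92 in HFD against ND PA, where 1 split gave as many as the real one, itself. The values were 1 and 1 between the macrophage subsets of HFD mice (2 splits as large, the real one included), 206 and 1 in WL against HFD CD11c+ ATM (1 split), and 644 and 0 in HFD ATDC against CD11c+ ATM (1 split).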

How the results depend on the processing

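Leaving out together 3 arrays that stood apart was chosen only after the results were seen. Of the named genes 0 changed direction past the threshold under any alternative. Counting a gene once for each comparison or interaction that named it, 407 values of named genes were past the threshold. Of these, 371 stayed past it without a filter, 387 with cyclic loess, 404 with the robust prior, 345 with array weights and 136 in fits of only the arrays compared, where 271 were lost. Of 165 camera calls, 160 held without a filter, 150 with cyclic loess, 21 with an estimated correlation and 74 with fry, and 0 changed direction. Where a leave-out left a lone array, it was assumed to vary like the other groups. For the counts below the cause was not tested, beyond fewer arrays giving fewer degrees of freedom.

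In the order HFD against ND CD11c- ATM, ATDC and PA, HFD subsets, WL against HFD CD11c+ and CD11c- ATM, WL against ND, WL subsets and ATDC against CD11c+ ATM, fits of only the arrays compared called 3, 0, 180, 0, 4, 31, 222, 1 and 392 genes, beside main counts of 95, 40, 401, 1, 206, 459, 957, 208 and 644. The interactions of 9 and 25 genes had 0 and 7. Beside the counts of 0, the fit of all arrays had 1335, 997 and 1123 genes at an unadjusted p under 0.05 in limma. Array weights gave 206 in HFD against ND CD11c- ATM, 1119 in PA, 26 for the HFD subsets, 173 in WL against HFD CD11c- ATM, 594 in WL against ND, 43 for the WL subsets and 1176 in ATDC against CD11c+ ATM. Without the 3 arrays these were 46 in HFD against ND CD11c- ATM, 96 in ATDC, 2 for the HFD subsets, 808 in WL against HFD CD11c- ATM, 405 for the WL subsets, 357 in ATDC against CD11c+ ATM and 14 for the HFD interaction. That interaction had 4 without a filter and 14 with cyclic loess.

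With 1 array left out, the counts ranged from 30 to 176 in HFD against ND CD11c- ATM, 18 to 81 in ATDC, 177 to 505 in PA, 0 to 3 for the HFD subsets, 23 to 771 in WL against HFD CD11c+ ATM, 199 to 570 in WL against HFD CD11c- ATM, 374 to 834 in WL against ND, 309 to 891 in ATDC against CD11c+ ATM, and 1 to 15 and 12 to 63 for the interactions. The 82 genes shared by HFD and WL against ND CD11c- ATM ranged from 26 to 135.

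Replicate numbers were not taken to pair the samples, since deviations of same-numbered arrays correlated between -0.13 and 0.25 and in no comparison were all of 3 pairs over 0.1. The mast cell list nevertheless had the same order of replicates (1, 3, 2) in all 4 HFD groups, and whether a number marks a shared pool is not given in the sources used here. With the number as a replicate block, 49 genes were called in HFD against ND CD11c- ATM and 2 in the HFD interaction, and with diet and number as a block 0 between the HFD subsets, against 1, and 72 between the WL subsets, against 208.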

Other observations

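The mast cell and eosinophil list stood higher on replicate 1 of each HFD group than on replicates 2 and 3: 4.05 in CD11c+ ATM, 4.31 in CD11c- ATM, 3.96 in ATDC and 3.29 in PA, against values from 2.30 to 3.02 on the other HFD arrays. T cell genes stood at 5.72 and 5.77 on the ND ATDC arrays and at 5.33, 4.38 and 4.55 on the HFD ATDC arrays. In WL against ND CD11c- ATM, 5 of 12 endothelial cell genes rose (7 adjusted over the list alone, camera adjusted p = 1.05e-07, adjusted p = 0.0405 with an estimated correlation), with 2 without ND replicate 1 and 1 without ND replicate 2 or WL replicate 2.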
